A study of Caenorhabditis elegans with 3 samples.

How the data were processed

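Gene expression was measured on Agilent long-oligonucleotide arrays with a Cy5 and a Cy3 channel. Each of 3 arrays carried RNA of the nasp-1/btr-1 mutant in 1 channel and of the N2 wild-type strain of Caenorhabditis elegans in the other. Per the labels, young adult hermaphrodites of both strains had been exposed to the pathogen Bacillus thuringiensis DB27 for 4 hours, about 200 animals were picked per replicate, and between 500 and 1000 ng of total RNA was labelled. The mutant is written btr-1 in some labels and nasp-1 / btr-1 in others, and both spellings were taken as 1 strain. The labels call the 3 arrays biological replicates, 1 to 3 of 3, but the labelling protocol speaks of 4 biological replicates. Why the numbers differ is not stated, so a replicate may be absent from the deposit. Replicates 1 and 2 had the mutant in Cy5, and replicate 3 was a dye swap with N2 in Cy5.

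The deposited values are log2 ratios of the Cy5 over the Cy3 channel, 1 per probe and array. The base of the logarithm and the direction are not stated in words: base 2 and Cy5 over Cy3 follow the convention of limma, the only tool the submitters' processing notes name, and the dyes follow the labels. The version of limma, the background correction, the normalization and the genome build are not given in the sources used here. The median deposited ratio was 0.01 on replicate 1, 0.00 on replicate 2 and 0.01 on replicate 3, so the arrays had been centred or normalized by the authors before deposit. The deposited column of replicate 3 correlated below 0 across probes with replicate 1 (Pearson r = -0.406) and with replicate 2 (r = -0.370), and its sign was turned, so that all ratios read mutant over N2. No channel intensities were used here, so dim or saturated spots were not filtered.

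Of 45220 entries per array, 1097 were empty on all arrays, which left 44123 probes. Through the platform's annotation, 27263 probes had 1 gene name, 0 had several and 16860 had none. Names were updated through accessions (19293 probes) or symbols (7970 probes) to a RefSeq gene table of assembly WBcel235, which changed the name on 98 probes, and its coordinates served only to find neighbouring genes. Probes of a gene were averaged on each array, giving 15078 genes, 10517 of them with 1 probe. Across the 1664 genes with exactly 2 probes, the mean ratios of both probes correlated with r = 0.625, against 0.005 after shuffling partners. No array-wide depth exists for such data, and the number of arrays limits the precision.

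Ratios were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors given as SD are over the 3 arrays, and errors given as SE are the moderated standard errors of limma. The same test was run on every probe. The 31 gene lists were tested with camera (preset correlation 0.01) where at least 5 members were measured, adjusted over 30 lists, and list members past the threshold were counted over all genes and adjusted over the list alone. Genes of multigene families and close paralogs, such as kgb-1 and kgb-2, nlp-28 to nlp-31, gst-26 and gst-27, F01D5.1 and F01D5.3, fipr-22 and fipr-23, btb-16 and btb-17 or the collagens, may share signal on each other's probes and are uncertain as single genes.

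Genes to be named were fixed by a rule before the data were examined: nasp-1 and dcr-1; the 10 largest mean rises and the 10 largest mean falls among genes past the threshold with the same sign on all arrays; and from each list up to 4 members past the threshold by smallest adjusted p, or at most 2 by smallest p where none passed. The genes mai-1, nlp-29, F53A9.8, lys-10, col-104, clec-4, clec-97, cyp-35A2, cyp-35A3, fat-7, elo-5, acdh-1, acdh-9, gst-10 and gst-36, and all genes in the closing observations that the rule does not take, were chosen after their values were seen. The tests, lists and alternatives were also fixed before the data were examined, apart from those listed as chosen later in the closing part.

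The alternatives were centring each array on its median, scaling the arrays to the same median absolute ratio, a dye term, estimated array weights, a robust variance prior, the median of the probes, genes with several probes, a requirement that all probes of a gene pass, a plain one-sample t statistic, an added 2-fold minimum, an adjusted p under 0.1, leaving out each replicate in turn, and, for lists, camera with an estimated correlation, fry and tests at probe level. The limma step was tested on 20 simulated data sets of this comparison, each with 15078 genes of which 200 had been changed. It recovered 0.800% of genes changed by 0.50 on the log2 scale, 44.3% of those changed by 1.00, 95.1% of those changed by 2.00 and 99.3% of those changed by 3.00, and 5.49% of its calls were false. In 20 simulated draws with the C-type lectins shifted by 0.30, camera called that list in 100% of draws and 0% of the other lists. Both simulations drew genes independently, with the spread of limma's fitted prior and without a dye effect. They do not show how often false calls arise where genes vary together or dyes matter. In the data, estimated correlations within lists reached 0.283 (ribosomal proteins), and the observed lectin median was 0.07, below the simulated shift. Tables were handled in Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1.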

Results

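The data were log2 ratios of transcript abundance in the nasp-1/btr-1 mutant over the N2 wild type of C. elegans, from 3 arrays with 1 biological replicate of each strain per array. Both strains had been kept on B. thuringiensis DB27, a bacterium that kills nematodes, for 4 hours before the RNA was taken. The single comparison of the design asked which transcripts differed between mutant and wild type under this exposure. Unexposed animals were not analysed here. The direction of all ratios rests on the dye labels and on the convention that deposited ratios are Cy5 over Cy3.

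The transcript of nasp-1 itself, which encodes a histone chaperone of the NASP family, had log2 ratios of -0.13, -0.04 and 0.16 on replicates 1, 2 and 3, with a mean of 0.00 ± 0.15 (SD, n = 3). The 95% confidence interval of the mean was -0.31 to 0.30 (limma adjusted p = 0.996). The labels do not give the nature of the mutation, so this transcript level is no check of the strain. The ratios of dcr-1, which encodes the endonuclease Dicer, were 0.14, -0.19 and -0.02, with a mean of -0.02 ± 0.16 (SD, n = 3, interval -0.33 to 0.29, adjusted p = 0.960).

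In the mutant, some genes for antimicrobial peptides, lysozymes and stress-activated kinases had lower transcript levels, while some collagen, lectin and glutathione S-transferase genes had higher levels. Most measured members of the lists that hold these genes did not pass, and some went the other way. Of 10 lys genes 2 fell and 1 rose, and of 243 C-type lectin genes 9 rose and 3 fell. The caenacin peptide gene cnc-4 was 15.3-fold lower (log2 -3.93 ± 0.56, SD, n = 3), the lysozyme gene lys-3 was 13.7-fold lower (log2 -3.77 ± 0.21) and the JNK-like kinase gene kgb-2 was 4.64-fold lower (log2 -2.21 ± 0.33). The intermediate filament gene ifc-1 was 3.71-fold higher (log2 1.89 ± 0.10) and the ammonium transporter gene amt-4 was 3.48-fold higher (log2 1.80 ± 0.38). Of 15078 genes, 185 were higher and 429 lower in the mutant at an adjusted p under 0.05 (limma), 614 in all. Each of these had the same sign on all 3 arrays, which a test of 3 values at this threshold favours by itself. Among all genes tested, 35.5% had the same sign on all 3 arrays, against 25% by chance. At least 2-fold changes were seen for 82 of the higher and 314 of the lower genes. Of the latter, 27 were at least 8-fold lower, while 0 genes were at least 8-fold higher. The median log2 ratio was 0.96 for the higher and -1.32 for the lower genes.

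**Figure D1:**
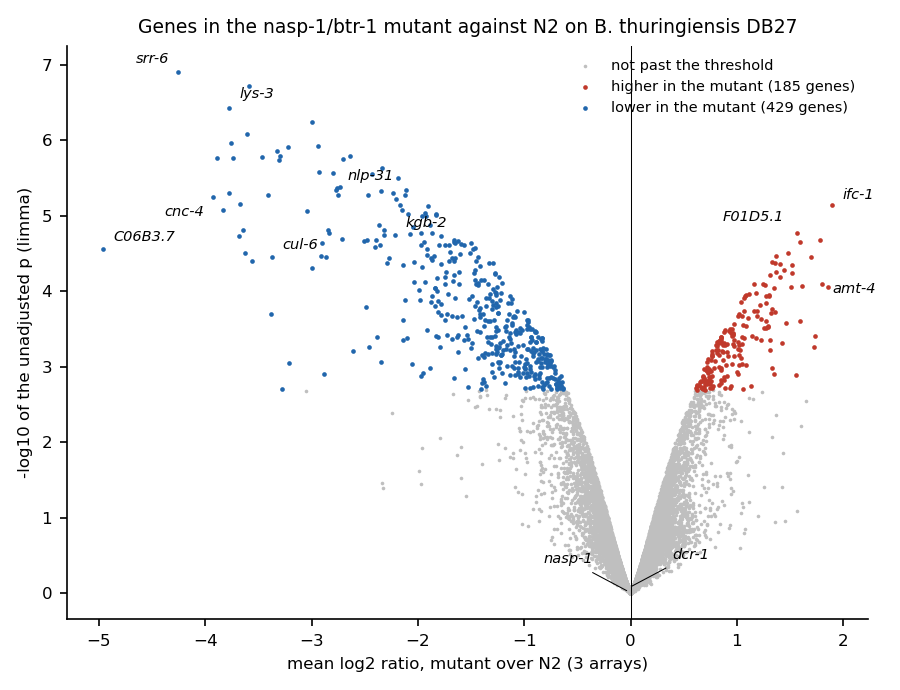
Mean log2 ratio of mutant over N2 on 3 arrays (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for 15078 genes, with the 185 higher genes in red, the 429 lower genes in blue and genes not past the threshold in grey. The lower genes reach a log2 ratio of -4.96 and the higher genes 1.89, and nasp-1 and dcr-1 lie near 0.

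The largest fall was that of C06B3.7 (log2 -4.96 ± 1.05, SD, n = 3, adjusted p = 0.00484), followed by srr-6, a serpentine receptor gene (-4.26 ± 0.15, adjusted p = 0.00143). After these came cnc-4 (adjusted p = 0.00256), F13A7.11 (-3.89 ± 0.40), F53B2.8 (-3.83 ± 0.60) and Y41C4A.32 (-3.78 ± 0.52). The others were lys-3 (adjusted p = 0.00172), the tetraspanin gene tsp-1 (-3.76 ± 0.33), K09D9.1 (-3.74 ± 0.38) and fipr-22 of the fungus-induced protein family (-3.68 ± 0.69). All 10 stayed past the threshold when any 1 replicate was left out.

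The largest rise was that of ifc-1 (adjusted p = 0.00297), followed by btb-16, which encodes a BTB domain protein (log2 1.85 ± 0.40, SD, n = 3, adjusted p = 0.00839). Next were amt-4 (adjusted p = 0.00803), the myo-inositol transporter gene hmit-1.1 (1.78 ± 0.21), and the collagen genes col-98 (1.73 ± 0.56) and col-93 (1.72 ± 0.60). They were followed by F09C8.1 (1.70 ± 0.24), Y49E10.18 (1.61 ± 0.31), the UDP-glucuronosyltransferase gene ugt-43 (1.6 ± 0.44) and F01D5.1 (1.6 ± 0.14). Of these 10, ifc-1 and hmit-1.1 stayed past the threshold when any 1 replicate was left out, and 8 lost the call without replicate 1.

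**Figure D2:**
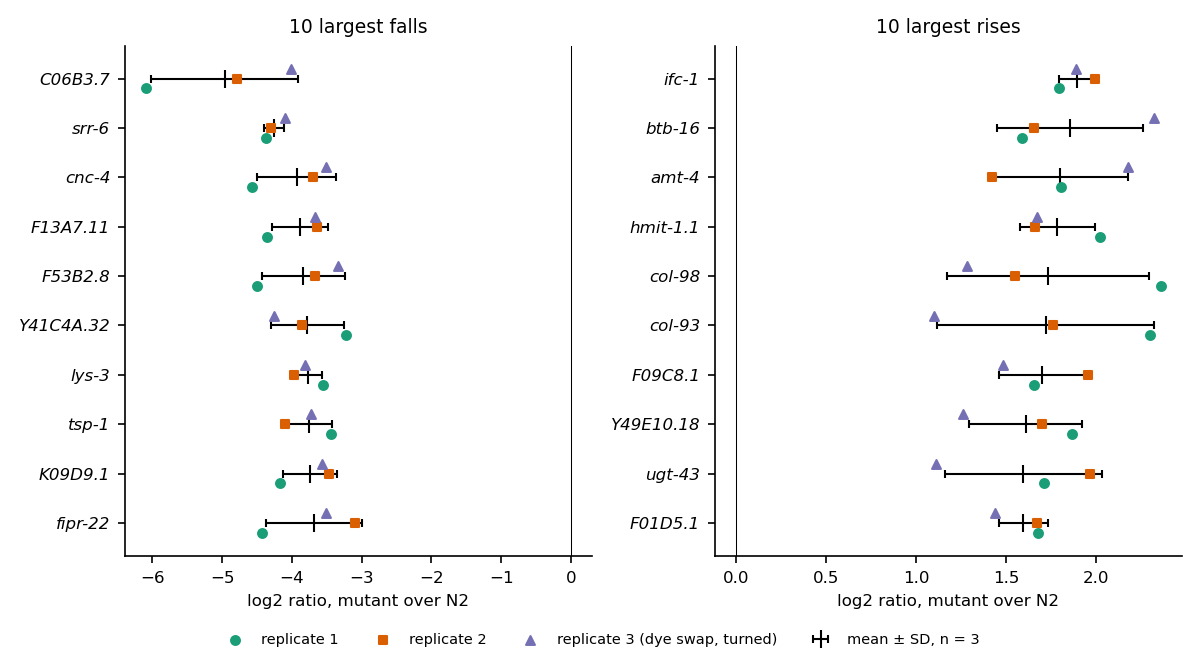
Log2 ratio of mutant over N2 (horizontal axes) for the 10 largest falls and the 10 largest rises, with 1 point per replicate and the mean ± SD over the 3 arrays in black. Every replicate lies on the same side of 0 for each of these genes, as the rule that chose them required. Replicate 3 is the dye swap after turning its sign.

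Of 28 measured genes of the p38, JNK and pore-forming toxin defence pathway, 6 fell, 0 rose and 22 did not pass. Beside kgb-2 the falls included its close relative kgb-1 (log2 -1.65 ± 0.22, SD, n = 3, adjusted p = 0.00525), tir-1, the adaptor upstream of p38 (-1.62 ± 0.31, adjusted p = 0.00803), and jun-1, a transcription factor of the AP-1 family (-0.90 ± 0.09, adjusted p = 0.0180). The 11 probes of jun-1 ran from -1.23 to -0.26 with 5 past the threshold. Its call was lost without replicate 1 (adjusted p = 0.153), 2 (0.0558) or 3 (0.0647). Adjusted over the list alone, 11 members were lower and 0 higher. The list had a median log2 ratio of -0.19, with medians of -0.48, -0.34 and -0.11 on replicates 1, 2 and 3 and -0.13 with a dye term. It was lower than other genes by camera (adjusted p = 2.96e-06), a call lost with an estimated correlation (adjusted p = 0.531). Among the 4 measured genes that make the glycolipid receptors of crystal toxins, bre-3, a glycosyltransferase gene, fell (-0.83 ± 0.06, adjusted p = 0.0202), and the other 3 did not pass. The bre-3 call was lost with a dye term (adjusted p = 0.0521) and without replicate 1 (0.174), 2 (0.0871) or 3 (0.0636). A list of this size was not given to camera.

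Of 11 measured neuropeptide-like antimicrobial peptide genes, 5 fell, 0 rose and 6 did not pass, and 6 were lower and 1 higher adjusted over the list alone. The falls were those of nlp-31 (log2 -2.76 ± 0.30, SD, n = 3, adjusted p = 0.00252), nlp-29 (-1.84 ± 0.47), nlp-30 (-1.48 ± 0.21), nlp-33 (-1.44 ± 0.30) and nlp-28 (-1.12 ± 0.14). The median of the list was -0.57 and its camera adjusted p, in the direction down, was 1.02e-04, against an adjusted p = 0.531 with an estimated correlation. Of 96 measured lysozyme, saposin-like and other antimicrobial genes, 10 fell and lys-10 rose (1.51 ± 0.28, adjusted p = 0.00839), and adjusted over the list alone 14 were lower and 5 higher. The falls included cnc-4, lys-3, fipr-22 and the cathepsin gene cpr-3 (-2.36 ± 0.41, adjusted p = 0.00455). This list had a median of 0.07 and a mean of -0.18 and did not pass as a list (camera, direction down, adjusted p = 0.747).

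Of 14 measured genes of the intracellular pathogen response, 3 fell and 0 rose, also adjusted over the list alone. These were Y41C4A.32 (adjusted p = 0.00252), the cullin gene cul-6 (log2 -2.86 ± 0.59, SD, n = 3, adjusted p = 0.00525) and skr-3, a Skp1-related gene (-0.99 ± 0.40, adjusted p = 0.0482). Cullins and Skp1-related proteins are subunits of ubiquitin ligases. The skr-3 call was lost after scaling (adjusted p = 0.0522), with a robust prior (0.0506), with a dye term (0.0529) and without replicate 1 (0.270) or 3 (0.116). The list was lower by camera (median -0.11, adjusted p = 0.0305), but not with an estimated correlation (adjusted p = 0.531), without replicate 2 (0.0558) or without replicate 3 (0.0570). Infection response genes named from pathogen screens went both ways, with 3 of 21 higher and 2 lower, and 8 higher and 5 lower adjusted over the list alone. F01D5.1, F01D5.3 (1.30 ± 0.21, adjusted p = 0.00965) and F55G11.8 (0.73 ± 0.17, adjusted p = 0.0423) rose, whereas zip-2, a bZIP transcription factor gene (-1.27 ± 0.42, adjusted p = 0.0249), and F53A9.8 (-0.92 ± 0.35, adjusted p = 0.0472, or 0.0528 after scaling) fell. The camera adjusted p of that list was 0.169.

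Of 170 measured cuticle collagen genes, 9 rose, col-104 fell (log2 -0.66 ± 0.13, SD, n = 3, adjusted p = 0.0481) and 160 did not pass. Adjusted over the list alone, 16 were higher and 3 lower. Examples beside col-98 and col-93 were col-103 (1.32 ± 0.39, adjusted p = 0.0198), col-135 (1.23 ± 0.27, adjusted p = 0.0147) and col-159 (1.06 ± 0.19, adjusted p = 0.0165). The median of the list was 0.10 and its camera adjusted p, in the direction up, was 0.00239, against an adjusted p = 0.531 with an estimated correlation. Of 243 measured C-type lectin genes, 9 rose, 3 fell and 231 did not pass, and 17 were higher and 5 lower adjusted over the list alone. The lectin genes clec-82 (1.29 ± 0.32, adjusted p = 0.0166), clec-50 (1.28 ± 0.30, adjusted p = 0.0149) and clec-172 (1.08 ± 0.04, adjusted p = 0.00965) rose, and clec-221 (-1.79 ± 0.63, adjusted p = 0.0222), clec-4 (-1.21 ± 0.47) and clec-97 (-0.69 ± 0.17) fell, the last with an adjusted p of 0.0502 once the arrays were centred. The lectin list had a median of 0.07 and a camera adjusted p of 0.0189 (direction up), which was 0.0514 with a dye term, while the adjusted p with an estimated correlation was 0.531. In a Fisher test chosen after the results were seen, clec genes were not over-represented among the higher genes (adjusted p = 0.0713).

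**Figure D3:**
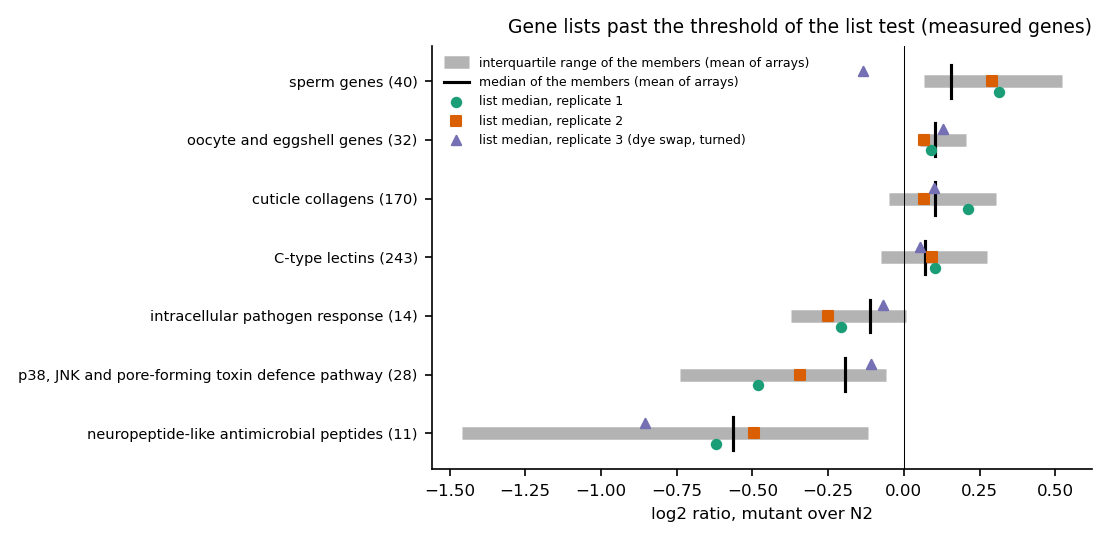
Log2 ratio of mutant over N2 (horizontal axis) of the 7 gene lists past the threshold of camera, with the median of each list on each replicate as points, the median of the members' mean ratios as a black bar and their interquartile range in grey. The sperm gene list is the list whose median on replicate 3, -0.14, lies on the other side of 0 from its medians on replicates 1 and 2, 0.32 and 0.29.

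Detoxification genes changed in both directions. Among 64 UDP-glucuronosyltransferase genes, 10 fell and 6 rose, and 13 were lower and 8 higher adjusted over the list alone. Here ugt-24 (log2 -1.83 ± 0.11, SD, n = 3, adjusted p = 0.00323), ugt-1 (-1.34 ± 0.33), ugt-16 (-1.27 ± 0.19) and ugt-31 (-1.27 ± 0.09) fell while ugt-43 rose (camera adjusted p = 0.346). Among 75 cytochrome P450 genes, 6 fell and 2 rose, the same counts as adjusted over the list alone. The falls included cyp-13A4 (-2.75 ± 0.32, adjusted p = 0.00252), cyp-33C8 (-2.47 ± 0.25), cyp-13A5 (-2.05 ± 0.25) and cyp-14A5 (-1.73 ± 0.46), and the rises were cyp-35A3 (0.86 ± 0.11) and cyp-35A2 (0.76 ± 0.04), with a camera adjusted p of 0.190 for the list. The 3 probes of cyp-13A5 ran from -3.17 to -0.07 with 2 past the threshold. Of 48 glutathione S-transferase genes, 5 rose and gst-22 fell (-1.62 ± 0.14, adjusted p = 0.00455), with 8 higher and 2 lower adjusted over the list alone. The rises were gst-26 (1.40 ± 0.13, adjusted p = 0.00560), gst-27 (1.27 ± 0.22), gst-10 (1.19 ± 0.22), gst-42 (1.08 ± 0.05) and gst-36 (0.85 ± 0.06), and the list as a whole did not pass (camera adjusted p = 0.0676).

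Of 63 fatty acid and lipid handling genes, 4 fell and 4 rose, and 7 were lower and 7 higher adjusted over the list alone (camera adjusted p = 0.0676). The desaturase genes fat-7 (log2 -2.89 ± 1.31, SD, n = 3, adjusted p = 0.0369) and fat-5 (-1.97 ± 0.29, adjusted p = 0.00455), the carnitine palmitoyltransferase gene cpt-4 (-2.39 ± 0.83) and the acyl-CoA synthetase gene acs-17 (-1.82 ± 0.41) fell. The elongase genes elo-6 (0.98 ± 0.22, adjusted p = 0.0219) and elo-5 (0.87 ± 0.17) and the acyl-CoA dehydrogenase genes acdh-1 (0.70 ± 0.16) and acdh-9 (0.65 ± 0.08) rose, acdh-1 with an adjusted p of 0.0609 by the median of its probes. Among 445 genes with F-box, MATH or BTB domains, 17 fell and 10 rose, with 22 lower and 11 higher adjusted over the list alone. The F-box genes fbxa-37 (-2.77 ± 0.31, adjusted p = 0.00252), fbxa-219 (-1.70 ± 0.26), fbxa-74 (-1.56 ± 0.13) and fbxa-14 (-1.24 ± 0.08) fell while btb-16 rose (camera adjusted p = 0.510).

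Small RNA and chromatin genes, to which dcr-1 and nasp-1 belong, had 1 member past the threshold. Of 39 genes of the RNA interference machinery, sid-2, whose product takes up double-stranded RNA from the gut, fell (log2 -0.84 ± 0.03, SD, n = 3, adjusted p = 0.0193) and 0 rose. The sid-2 call was lost with a dye term (adjusted p = 0.0511) and without replicate 1 (0.167), 2 (0.0788) or 3 (0.0647). Adjusted over the list alone 1 was lower, and the camera adjusted p was 0.747. Of 7 targets of endogenous small RNAs of the ERGO-1 class, 0 passed over all genes and 2 were higher adjusted over the list alone. The lowest p-values were those of ZK380.5 at 0.85 ± 0.38 (adjusted p = 0.0679) and fbxb-97 at 0.40 ± 0.08 (adjusted p = 0.166). The 2 probes of fbxb-97 differed, at -0.10 and 0.90, with 1 of them past the threshold in the fit of all probes. The list had a camera adjusted p of 0.0676, which passed in the direction up with a dye term (0.0482) and without replicate 1 (0.0457). In limma, 0 of 25 histone genes, 0 of 28 histone chaperone and chromatin assembly genes and 0 of 30 DNA replication and cell cycle genes passed, over all genes or adjusted over the list alone. The lowest p-values among histones belonged to his-72 (0.39 ± 0.08, adjusted p = 0.177) and his-41 (0.39 ± 0.10, adjusted p = 0.189). Among the chaperone and assembly genes they belonged to mes-3 (-0.27 ± 0.16, adjusted p = 0.402) and met-2 (-0.25 ± 0.14, adjusted p = 0.448), and among replication genes to rnr-2 (0.31 ± 0.02, adjusted p = 0.280) and pcn-1 (0.27 ± 0.16, adjusted p = 0.406). Camera gave these 3 lists adjusted p-values of 0.981, 0.940 and 0.142.

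Among germline and embryo lists, single genes passed the threshold in the embryonic list alone. Of 32 oocyte and eggshell genes 0 passed, also adjusted over the list alone, with egg-1 at log2 0.39 ± 0.12 (SD, n = 3, adjusted p = 0.198) and oma-2 at 0.39 ± 0.44 (adjusted p = 0.441). The list was higher by camera (median 0.10, adjusted p = 0.0305), but not without replicate 3 (0.187) or with an estimated correlation (adjusted p = 0.531). Of 40 sperm genes 0 passed by either adjustment, with spe-6 at 0.49 ± 0.20 (adjusted p = 0.136) and spe-12 at 0.42 ± 0.26 (adjusted p = 0.259). The sperm list was higher by camera (median 0.16, adjusted p = 0.0108), with medians of 0.32, 0.29 and -0.14 on replicates 1, 2 and 3. That call was lost without replicate 1 (0.163), without replicate 2 (0.0861) and with an estimated correlation (adjusted p = 0.660). Of 37 P granule and germline nucleus genes 0 passed by either adjustment (camera adjusted p = 0.510), with rec-8 at 0.38 ± 0.23 and meg-1 at 0.23 ± 0.06. Neither did any of 6 yolk protein genes (camera adjusted p = 0.651), with vit-1 at 0.53 ± 0.21 and vit-3 at -0.38 ± 0.19. The list of 60 early embryonic zygotic regulators held 34 sdz genes, which were taken by name and not by known function. In this list sdz-35 (-1.09 ± 0.18, adjusted p = 0.0140) and pha-4 (-0.78 ± 0.14, adjusted p = 0.0302) fell and 0 rose. The 2 probes of sdz-35 were at -1.54 and -0.64, with 1 past the threshold. The 5 probes of pha-4 ran from -2.1 to 0.06 with 2 past the threshold, and its call was lost with their median (adjusted p = 0.141), with a dye term (0.0681) and without replicate 1 (0.227), 2 (0.106) or 3 (0.0741). Adjusted over the list alone, 5 were lower and 1 was higher (camera adjusted p = 0.319).

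Among tissue markers, 2 of 19 intestine genes rose and 0 fell. These were the proton pump subunit gene vha-6 (log2 0.88 ± 0.07, SD, n = 3, adjusted p = 0.0182) and the intermediate filament gene ifc-2 (0.66 ± 0.09, adjusted p = 0.0423). The 4 probes of ifc-2 ran from 0.12 to 0.98 with 2 past the threshold. Adjusted over the list alone, 5 intestine genes were higher and 2 lower (camera adjusted p = 0.0676). Of 23 body wall muscle genes 0 passed by either adjustment (camera adjusted p = 0.651), with tni-1 at 0.64 ± 0.20 (adjusted p = 0.0671) and dim-1 at 0.42 ± 0.12 (adjusted p = 0.161). The pharynx list of 74 genes held 51 pqn and 10 abu genes, which were taken by name and not by where they are expressed. In this list pqn-88 rose (1.05 ± 0.24, adjusted p = 0.0193) and pqn-89 (-1.47 ± 0.33, adjusted p = 0.0116) and pqn-92 (-0.78 ± 0.10, adjusted p = 0.0251) fell. All of these are pqn genes, so the calls need not speak of the pharynx. Adjusted over the list alone the counts were 1 higher and 2 lower (camera adjusted p = 0.909). Of 102 neuron genes, the syntaxin gene unc-64 fell (-0.94 ± 0.28, adjusted p = 0.0313), 0 rose and 0 passed adjusted over the list alone (camera adjusted p = 0.306).

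Stress and housekeeping lists had 0 members past the threshold over all genes. Of 18 unfolded protein response genes, 0 passed adjusted over the list alone either. The lowest p-values were those of xbp-1 (log2 -0.64 ± 0.20, SD, n = 3, adjusted p = 0.0671) and hsp-3 (-0.49 ± 0.06, adjusted p = 0.0937), with a camera adjusted p of 0.0676. Of 26 heat shock and oxidative stress genes, 3 were lower and 0 higher adjusted over the list alone. The gene hsp-17 was at -0.67 ± 0.20 (adjusted p = 0.0616) and mtl-2 at -0.58 ± 0.15 (adjusted p = 0.0752), with a camera adjusted p of 0.134. Of 25 genes of the mitochondrial respiratory chain, 2 were higher and 0 lower adjusted over the list alone. The gene gas-1 was at 0.58 ± 0.11 (adjusted p = 0.0651) and ucr-2.2 at 0.69 ± 0.26 (adjusted p = 0.0683), with a camera adjusted p of 0.0676. Of 58 ribosomal protein genes, 0 passed adjusted over the list alone. The gene rpl-13 was at -0.47 ± 0.11 (adjusted p = 0.117) and rpl-11.2 at 0.36 ± 0.19 (adjusted p = 0.272), with a camera adjusted p of 0.917.

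Single probes gave 522 higher and 1043 lower of 44123. Of the 170 genes past the threshold that had several probes, all probes passed for 69 and none for 9, and 0 genes had probes past the threshold in both directions. Across genes, which are not independent replicates, the ratios of replicates 1 and 2 correlated with r = 0.645, those of replicates 1 and 3 with r = 0.467 and those of replicates 2 and 3 with r = 0.423 (Pearson). The number of genes past the threshold depended on every array, with 3 higher and 95 lower without replicate 1, 83 and 298 without replicate 2, and 93 and 252 without replicate 3. Of the 614 genes, 91 passed in all of these fits. Among the 86 genes named here as past the threshold these were the 10 largest falls, ifc-1, hmit-1.1, cpr-3, nlp-31, kgb-2, cul-6, cyp-13A4, cyp-33C8, cyp-13A5, ugt-24, fat-5, fbxa-37 and mai-1, while the other 63 lost the call without replicate 1. With a dye term the number was 371, of which 338 were among the 614. The named genes lost with it were col-98, col-103, col-104, sid-2, pha-4, ifc-2, pqn-92, unc-64, clec-4, clec-82, clec-97, clec-221, zip-2, F55G11.8, bre-3, skr-3, cyp-14A5, cyp-35A2, nlp-29, fat-7, elo-5, acdh-1, acdh-9 and gst-36.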

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

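Probes without a gene name, which enter none of the gene comparisons, also held values past the threshold. Of 16860 such probes, 580 passed the threshold in the limma fit of all probes, 264 of them higher and 316 lower in the mutant. They stand here because they are data that the comparisons of genes leave out. With the sign of any 1 replicate flipped 0 passed, a check chosen after the result was seen, and the 4 sign patterns of 3 arrays are too few for a share under 0.05. The median log2 ratio was 1.31 for the higher and -1.47 for the lower of these probes, and their extremes were 3.33 and -4.53. Which genes they measure was not analysed here, and no explanation was tested.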

How the results depend on the processing

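The count of genes past the threshold was 614, with 185 higher and 429 lower. It was 604 after centring each array, 621 after scaling, 603 with a robust prior, 618 with the median of the probes, 839 with array weights (273 higher) and 478 where all probes had to pass. It was 371 with a dye term (99 higher, 272 lower) and 316 among the 4561 genes with several probes (121 higher, 195 lower), of which the main fit had called 170; that refit has its own variance prior and adjusts over fewer genes. An added 2-fold minimum left 396 (82 higher), and an adjusted p under 0.1 gave 969 (360 higher). A plain one-sample t statistic called 0 genes, against 1751 at an unadjusted p under 0.05 and 2208 for limma. Leaving out 1 replicate gave 98 to 381.0 genes, 3 to 93 higher and 95 to 298 lower, with fewer arrays behind each fit. Probes past the threshold numbered 1565, 1550 after centring and 1127 with a dye term.

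Of the 86 genes named as past the threshold, 63 lost the call without replicate 1, 18 without replicate 2, 34 without replicate 3, 24 with a dye term and 86 with the plain statistic; none of the named genes that passed in any setting changed direction between settings. For the list calls, an estimated correlation gave camera adjusted p-values of 0.531, and 0.660 for sperm genes. That setting leaves camera the 2 residual degrees of freedom of 3 arrays. The estimates were -6.56e-05 for neuropeptide-like, -0.0613 for pathogen response and 0.00956 for lectin genes, below the preset 0.01. A correlation above the preset value thus did not cost these lists their calls, while the estimates of the other called lists were above it. Fry, which tests whether the genes of a list move one way and not whether they differ from other genes, gave 0.0703 for the antimicrobial neuropeptide-like and pathogen response lists, 0.169 for the toxin defence list, 0.189 for oocyte, collagen and lectin genes and 0.450 for sperm genes. Lectin genes reached 0.0514 with a dye term. Without 1 replicate the adjusted p of oocyte genes ran from 0.0328 to 0.187, of sperm genes from 5.41e-07 to 0.163 and of pathogen response genes from 0.0204 to 0.0570 (0.0558 without replicate 2). The cause of the losses was not tested further. Lists that passed by camera under an alternative alone were ERGO-1 targets (0.0482 with a dye term, 0.0457 without replicate 1), intestine genes (0.0457 without replicate 1), glutathione S-transferases (0.0165 without replicate 2) and, without replicate 3, infection response (0.0351), unfolded protein response (0.0357) and lipid genes (0.00583). Spearman correlations between arrays were 0.459 (replicates 1 and 2), 0.191 (1 and 3) and 0.146 (2 and 3); over genes outside the interquartile range of the mean ratio, Pearson r was 0.731, 0.583 and 0.548. No paired analysis was possible because the design has 1 group, and each array already holds both strains of a replicate.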

Other observations

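Of the tests in this part, the family enrichment, the dye, tissue share, family name and sperm tests were chosen after the results were seen; the sign flips, the neighbour count and the window around nasp-1 were not. Beyond the fixed lists, gene families with at least 10 measured members were tested for an excess of called genes (Fisher's exact test, one-sided, 224 tests). This test counts genes as independent, but members of a family may vary together or share signal on each other's probes. Its p-values may therefore be too small. Nuclear hormone receptor genes were over-represented among the lower genes, with 19 of 267 (adjusted p = 0.0107). These included nhr-3 (log2 -2.04 ± 0.19, SE), nhr-112 (-1.73 ± 0.22), nhr-202 (-1.62 ± 0.23) and nhr-231 (-1.51 ± 0.12). P-glycoprotein transporter genes were lower in 4 of 14 cases (adjusted p = 0.0184): pgp-6 (-2.12 ± 0.22), pgp-5 (-1.65 ± 0.17), pgp-7 (-1.61 ± 0.14) and pgp-9 (-1.29 ± 0.13).

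Some families already listed by function were over-represented too: ugt genes among the lower (10 of 64; adjusted p = 0.00269) and the higher genes (6 of 64; 0.00973), fbxa genes among the lower (16 of 190; 0.00973), gst genes among the higher (5 of 43; 0.00973), col genes among the higher (8 of 152; 0.0184) and nlp genes among the lower (6 of 41; 0.0277). Others were not, such as clec (9 of 243; 0.0713), acdh (2 of 13; 0.199) and btb genes (2 of 21; 0.403) among the higher and cyp (6 of 75; 0.317), lys (2 of 10; 0.437) and cnc genes (2 of 11; 0.494) among the lower. The gene mai-1 was measured by a pair of probes that differed: log2 -4.97 ± 0.37 (SD, n = 3) on the first and 0.30 ± 0.21 on the other.

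The real signs of the arrays called 614 genes and the highest of the other sign patterns 0, so that 1 of the 4 patterns gave as many; 4 patterns are too few for a share under 0.05.

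The toxin defence and antimicrobial neuropeptide-like lists were lower by camera with the preset correlation. With a dye term both stayed so, with the higher adjusted p at 0.000915, and 8 of their 11 called members stayed past the threshold. All called genes had the same sign on all 3 turned arrays, so that their staying was favoured beforehand. Both lists were also picked for being low on these arrays, so neither result decides on dye bias. On replicate 3 alone, 17 of 28 toxin defence genes were below 0 (exact binomial p = 0.345) and 9 of 11 neuropeptide-like genes (p = 0.0654), which decides nothing. A smaller share of a tissue's RNA would lower its markers, and neither marker median was below 0. The median of the intestine markers was 0.18 (95% bootstrap interval -0.08 to 0.41), above that of the toxin defence list by 0.073 to 0.885. For epidermis, the median of the collagens was 0.10 (0.06 to 0.16), above that of the neuropeptide-like list by 0.062 to 1.6. These differences decide nothing, since the toxin defence and neuropeptide-like lists were picked for being low. The bootstrap also resamples genes and not animals. Both lists lost their camera call with an estimated correlation (adjusted p = 0.531). Whether the strains differ in their response to the pathogen or also without it was not tested, since unexposed animals were not analysed here.

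Genes lower in the mutant lay next to each other on the chromosomes more often than chance gives: 47 neighbouring pairs, against a mean of 12.1 and a highest value of 27 in 10000 shuffles (permutation p = 0.0001, the smallest these can give). The higher genes did so too, with 13 pairs against a mean of 2.26 and a highest value of 9 (permutation p = 0.0001). Apart from the window around nasp-1, the tests below concern the lower genes. Runs of 4 were nlp-31, nlp-30, nlp-29 and nlp-28, and ZK896.1, ZK896.5, ZK896.4 and K08D8.6, and also Y17D7B.3, Y17D7B.2, nhr-231 and nhr-170, and F53A9.1, F53A9.6, F53A9.7 and F53A9.8. A background segment linked to nasp-1 would concentrate calls there, but nasp-1 and the 50 measured genes on each side held 4 called genes of either direction, the median of all such windows. Larger segments around nasp-1 and background segments elsewhere were not tested. The pairs may come from response genes that sit in clusters, or from near-identical copies read by each other's probes; without the 13 pairs that share a family name 34 remained (shuffles at most 25), but copies with only sequence names keep the latter open.

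Sperm genes differed between arrays, with turned medians of 0.32, 0.29 and -0.14. A strain difference shared by the 3 replicates would by itself raise them on every array, but 27 of 40 lay below 0 on replicate 3 (exact binomial p = 0.0385, counting genes that may vary together as independent). With a dye term the list stayed higher in the mutant (camera adjusted p = 0.00998, median strain coefficient 0.10), but without that term the call was lost with an estimated correlation (adjusted p = 0.660) and without replicate 1 (0.163) or 2 (0.0861), so a strain difference beside a dye effect is neither shown nor excluded. The median dye coefficient of these genes was 0.184, above 100% of 10000 random lists of the same size. That rank decides nothing, since the list was picked for its change of sign on replicate 3, which the coefficient measures. Random lists also lack the correlation within the sperm list, estimated at 0.256. Dye bias of the sperm gene probes and a different sperm content of the animals in replicate 3 give the same signs and cannot be told apart with 1 dye-swap array. Medians of lists that camera did not call also changed sign on replicate 3. Those of ribosomal protein genes were 0.03, 0.06 and -0.13, with 48 of 58 genes below 0 on replicate 3 (exact binomial p = 4.52e-07). This p is too small to be taken as it stands. It counts genes as independent, though their estimated correlation was 0.283, and the list was picked for its change of sign. Infection response genes had 0.44, 0.29 and -0.15, while body wall muscle genes went the other way (-0.09, -0.05 and 0.15). The reversal was thus not particular to sperm genes, and its cause in the other lists was not tested.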
